A study of Homo sapiens with 9 samples.

How the data were processed

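Polyadenylated RNA was measured in 9 libraries of H9 human embryonic stem cells taken through neuroepithelial induction, 3 on a flat plate, 3 on a concave one and 3 on a convex one. Per the labels, total RNA was treated with DNase, mRNA was purified with poly-T beads, and strand-specific libraries were made with Illumina TruSeq reagents. The authors' deposited values are raw counts per gene, made with HISAT2 and featureCounts on GRCh38 per the labels. Versions, annotation release and strand setting are not given in the sources used here. The table covers the whole series, and each column was matched to its library by group and replicate number. All 9 columns are whole numbers, and 0 other per-sample columns were left aside. Each library held between 49420082 and 64763412 counts.

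Of 62710 Ensembl gene identifiers, 62639 were found in the table of gene names and 58274 in GENCODE v29, from which coordinates, gene types and transcript lengths were taken. The 71 without a name held at most 0.0109% of a library's counts. No pair of libraries in a group differed by as little as sampling noise: the chi-square per degree of freedom between replicates ran from 19.7 to 284.6, over genes with at least 10 counts in a pair.

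Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 9 libraries, with a common biological coefficient of variation of 0.329. Each pair of groups was compared, as the series' design text describes, and an F test compared the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called, with no fold minimum. CPM values were computed with TMM-scaled library sizes. All tests were two-sided. Over the 3 comparisons and the F test, 4 families of gene tests were adjusted separately.

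A total of 35 gene lists were tested with limma's camera, preset inter-gene correlation 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and beside it with an estimated correlation and with fry. Lists with fewer than 5 tested members were not to be tested; all 35 had more. Of the listed symbols 1 (DDX58) was not matched. The lists' members were also adjusted over the list alone. Several lists share members, among them ISL1, HAND1 and CCN2. Early neuroectoderm and pluripotency lists hold genes that the cultures are meant to express, and the other lineage lists hold markers of cells they could contain.

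Genes named in the text were chosen by rule: up to 10 called genes per direction with at least 5 CPM on average and no overlap between the groups; where none was called, the 3 with the smallest p per direction and at least 5 CPM on average; up to 4 members with the smallest p of each called list; and PAX6, SOX2, OTX2, POU5F1, NANOG, CDH1, CDH2, SHROOM3, CCN1 and CCN2 always. Not every gene the rule selects is reported here. The design, lists, naming rule and main alternatives were fixed before the data were examined.

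The groups share replicate numbers, so the numbers were checked for pairing by correlating each library's deviation from its group mean across genes. For numbers 1, 2 and 3 the Pearson r was 0.379, 0.0211 and 0.338 between flat and concave, 0.372, 0.397 and 0.62 between flat and convex, and 0.579, 0.29 and 0.612 between concave and convex. With a minimum of 0.1 for every number, the numbers paired flat with convex and concave with convex, not flat with concave. Some libraries of unlike number also passed 0.1, among them flat 2 with convex 1 (r = 0.229) and concave 2 with convex 1 (r = 0.199). Deviations within a group cancel out, so a deviation shared by the libraries numbered 3 can make those numbered 1 and 2 correlate. The minimum alone therefore does not show that numbers 1 and 2 were paired. Values with the replicate number as a block are printed for all of them.

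Alternatives were DESeq2 size factors, library size only and upper-quartile factors in place of TMM, no filter beyond 1 count, a filter of at least 1 CPM in 3 libraries, DESeq2, limma voom, the 6 libraries of a comparison alone, the replicate block, other thresholds, and each library left out in turn. Further alternatives were chosen after seeing the data: a term for the libraries numbered 3, libraries numbered 1 and 2 only, flat 2 and concave 1 left out together, voom with library quality weights, a correction for transcript length, alone or with the block, and an estimated correlation in the gene set tests with the block. That correction subtracted a lowess curve (span 0.3) of each gene's log2 deviation on log2 transcript length in each library, for the 95.1% of tested genes with a length. The length was first taken as the union of exons and was changed, after a first run, to the median over a gene's principal transcripts.

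The comparisons with flat share its libraries, so their correlation was set beside 20 simulations of unchanged groups. These took log2 CPM deviations with each group's own spread per gene, without or with the covariance by replicate number, and were chosen after seeing the data. Splits of the libraries were recounted, all 10 for each pair of groups and all 27 that set 1 library of each group apart. For the 3 groups 40 splits were drawn instead of 100 to keep the run short. The whole procedure was tested on simulated counts with 200 changed genes and 1 list shifted by 0.5 log2 units. It called 4, 6 and 3 unchanged genes in concave against flat, convex against flat and concave against convex, and found the shifted list in all 3, also with an estimated correlation, and 0 other lists. Genes were drawn independently there, whereas the correlation estimated in the data was 0.969 for the shifted list, cytosolic ribosomal proteins, in concave against flat. The simulation therefore does not measure how often the list tests find or falsely call lists in these data.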

Results

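RNA was sequenced from early neuroepithelial cultures made from H9, an established human embryonic stem cell line. Cells spent 72 h in pluripotency medium on a Matrigel-coated silicone (PDMS) plate and 48 h under dual SMAD inhibition, in which SB431542 and LDN block receptors of the TGF-beta and BMP families. The plate was then bent to a concave or a convex shape, or left flat as the control, for a further 24 h under the same inhibitors. Each group had 3 libraries, 9 in all. Counts summed to 57742852, 49420082 and 59511953 in flat libraries 1, 2 and 3. They summed to 64763412, 62216830 and 51916974 in the concave libraries and to 64352611, 63797258 and 58640365 in the convex ones. Of 62710 genes in the table, 23075 had enough counts to be tested. The median standard error of a log2 fold change was 0.221 for genes averaging at least 5 CPM, counts scaled to library size and TMM factor. Gene positions are those of GRCh38 (GENCODE v29). Values are CPM as mean ± SD, with n = 3 libraries per group.

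The cultures of every group held abundant mRNA of the transcription factors SOX2, OTX2 and POU5F1, with little PAX6 and almost no NANOG. SOX2 (ENSG00000181449, chromosome 3, 181711924 to 181714436) stood at 713 ± 124 CPM in flat, 666 ± 133 in concave and 665 ± 169 in convex cultures, and OTX2 (ENSG00000165588, chromosome 14, 56799905 to 56810479) at 289 ± 4.99, 288 ± 30.7 and 278 ± 11.6. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) was still abundant, at 401 ± 98.5, 315 ± 157 and 317 ± 143 CPM, whereas NANOG (ENSG00000111704, chromosome 12, 7787794 to 7799141) was close to the floor, at 0.122 ± 0.169, 0.0621 ± 0.108 and 0.174 ± 0.262. PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062) was low, at 2.42 ± 1.81, 3.54 ± 2.63 and 3.82 ± 3.04 CPM. E-cadherin, CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), gave 358 ± 226, 383 ± 219 and 362 ± 243 CPM and N-cadherin, CDH2 (ENSG00000170558, chromosome 18, 27950966 to 28177446), 141 ± 26.8, 169 ± 61.4 and 169 ± 72.8. The apical constriction gene SHROOM3 (ENSG00000138771, chromosome 4, 76435100 to 76783253) stood at 72.5 ± 32.5, 75.9 ± 13.1 and 84.04 ± 21.4 CPM. The YAP target CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373) gave 13.1 ± 11.4, 20.9 ± 24.3 and 23.6 ± 26.7, and CCN1 (ENSG00000142871, chromosome 1, 85580761 to 85583962) 23.8 ± 16.9, 33.01 ± 33.5 and 35.3 ± 33.2. None of these 10 genes passed the test between any pair of groups (edgeR adjusted p of at least 0.874 for concave against flat, 0.728 for convex against flat and 1 for concave against convex). POU5F1 was higher in the flat library than in both curved libraries of the same number, for each number, and did not pass with the number as a block either (edgeR adjusted p = 0.506 for concave and 0.264 for convex against flat). POU5F1 has several processed pseudogenes, whose reads can be counted for it or lost from it.

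**Figure D1:**
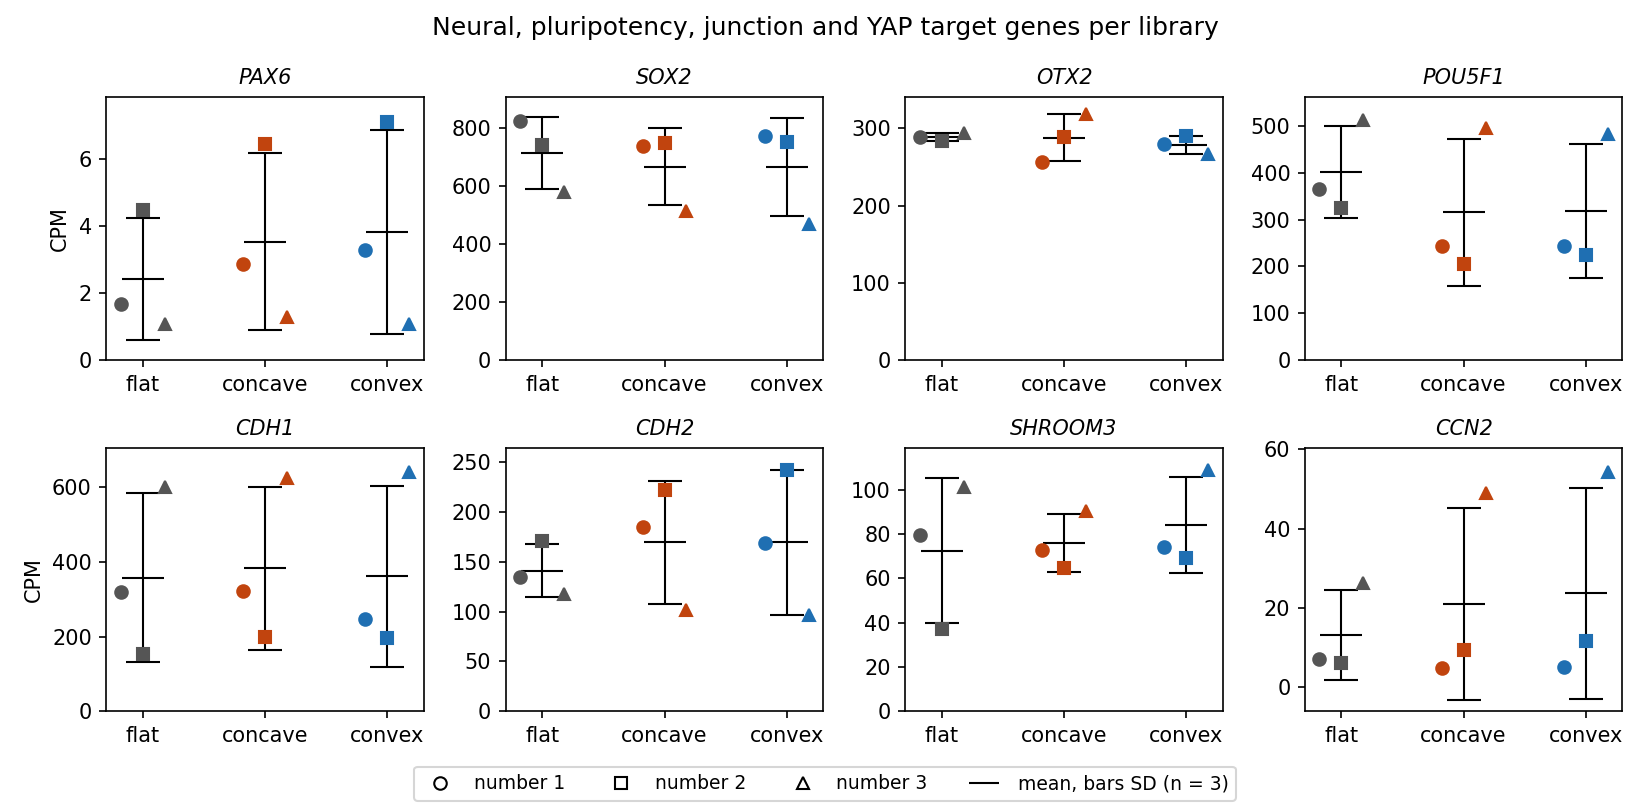
CPM of PAX6, SOX2, OTX2, POU5F1, CDH1, CDH2, SHROOM3 and CCN2 in the 9 libraries, by group (long line, mean; capped bars, SD of 3 libraries; marker shape, library number). SOX2, OTX2 and POU5F1 were abundant in every group, PAX6 averaged at most 3.82 CPM, and libraries numbered 3 lay apart within each group for CDH1 and CCN2.

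Many genes followed the replicate number in the labels, and 0 passed edgeR's F test among the plate shapes (897 at an unadjusted p under 0.05; DESeq2 and limma voom also called 0). The library farthest from the others was flat 2: the chi-square per degree of freedom of its counts was 133.1 against flat 1 and from 240.3 to 383.5 against the other 7, and at most 160.7 in pairs without it. The first principal component of log2 CPM held 44.6% of the variance and the second 24.6%. With the group as a term, 3756 genes differed between the 3 libraries numbered 3 and the other 6 (edgeR adjusted p under 0.05; 1752 higher, 2004 lower). The libraries numbered 3 were set apart after they were seen to differ, and no p-value of this comparison allows for that choice. Pluripotency mRNAs were higher in libraries numbered 3: 14 of 24 tested list members were called higher and 0 lower (camera adjusted p = 2.47e-14; adjusted p = 0.0101 with an estimated correlation). TDGF1 (ENSG00000241186, chromosome 3, 46574534 to 46582463) reached 159.5 ± 34.9 against 2.704 ± 1.46 CPM (log2 difference 5.90, edgeR adjusted p = 6.91e-05), L1TD1 (ENSG00000240563, chromosome 1, 62194831 to 62212328) 526 ± 54.8 against 179.6 ± 43.3 CPM and POU5F1 496 ± 15.5 against 268 ± 62.5 CPM, over 3 and 6 libraries. Early neuroectoderm mRNAs were lower, 14 of 23 members called lower and 0 higher (camera adjusted p = 1.94e-08; adjusted p = 0.28 with an estimated correlation), with SIX3 (ENSG00000138083, chromosome 2, 44941898 to 44946077) at 33.8 ± 10.2 against 154 ± 36.2 CPM. Among them DLK1 (ENSG00000185559, chromosome 14, 100725705 to 100738224) stood at 113 ± 57.2 against 887 ± 444 CPM, LIX1 (ENSG00000145721, chromosome 5, 97091867 to 97142872) at 1.71 ± 0.392 against 19.9 ± 8.899 CPM and PAX6 at 1.17 ± 0.121 against 4.31 ± 2.12 CPM. Markers of other cell types moved as well, with medians of 0.89 for non-neural ectoderm, 0.86 for amnion and trophectoderm and -1.22 for fibroblast, endothelial and blood (adjusted p = 0.219, 0.101 and 0.101 with an estimated correlation). By fry these 3 lists passed (adjusted p = 0.00615, 0.000641 and 0.000641), as did early neuroectoderm (fry adjusted p = 0.0109). CDH1 was higher at 622 ± 19.98 against 240.1 ± 69.3 CPM and CDH2 lower at 105 ± 11.1 against 187 ± 38.9 CPM. Of YAP targets, CCN1 stood at 62.6 ± 16.9 against 14.7 ± 3.91 CPM and CCN2 at 43.1 ± 14.9 against 7.25 ± 2.66 CPM. The count of genes was 1048 without convex 3, 2163 without convex 1, 2331 without flat 3 and 2383 without concave 3, and from 2552 to 5402 without each of the other libraries. Setting the libraries numbered 1 or those numbered 2 apart in the same way called 0 genes each, with 2252 and 1542 at an unadjusted p under 0.05 (edgeR). The other 6 libraries then held those numbered 3, whose difference adds to the spread. These counts therefore do not show that numbers 1 and 2 were alike.

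**Figure D2:**
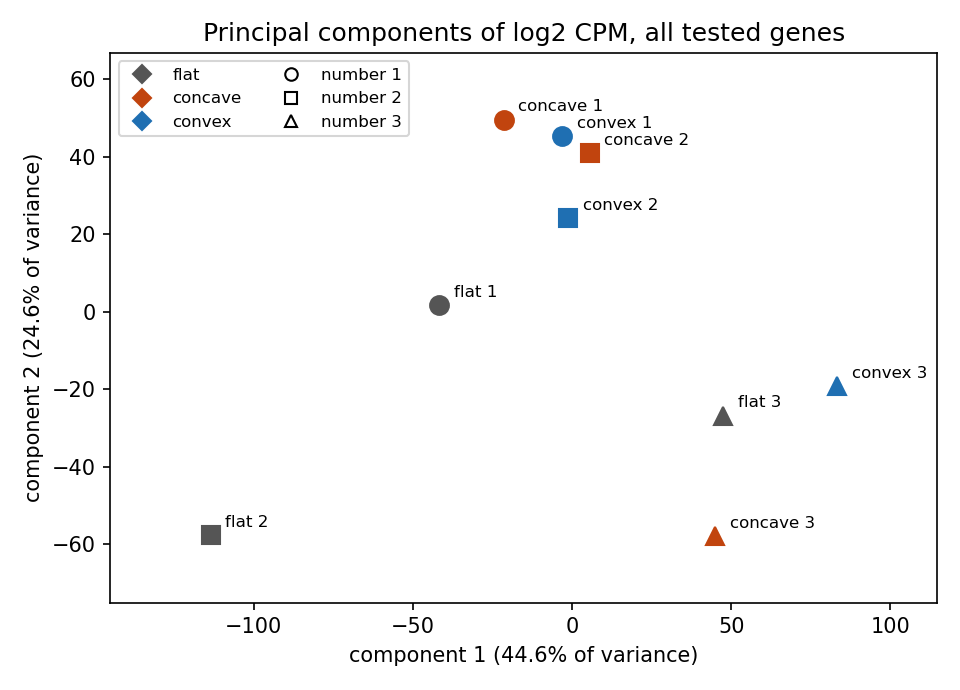
The 9 libraries on the first (44.6% of variance) and second (24.6%) principal components of log2 CPM, coloured by group and labelled by number. Flat 2 lay at -113.5 and convex 3 at 83.3 on the first component.

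**Figure D3:**
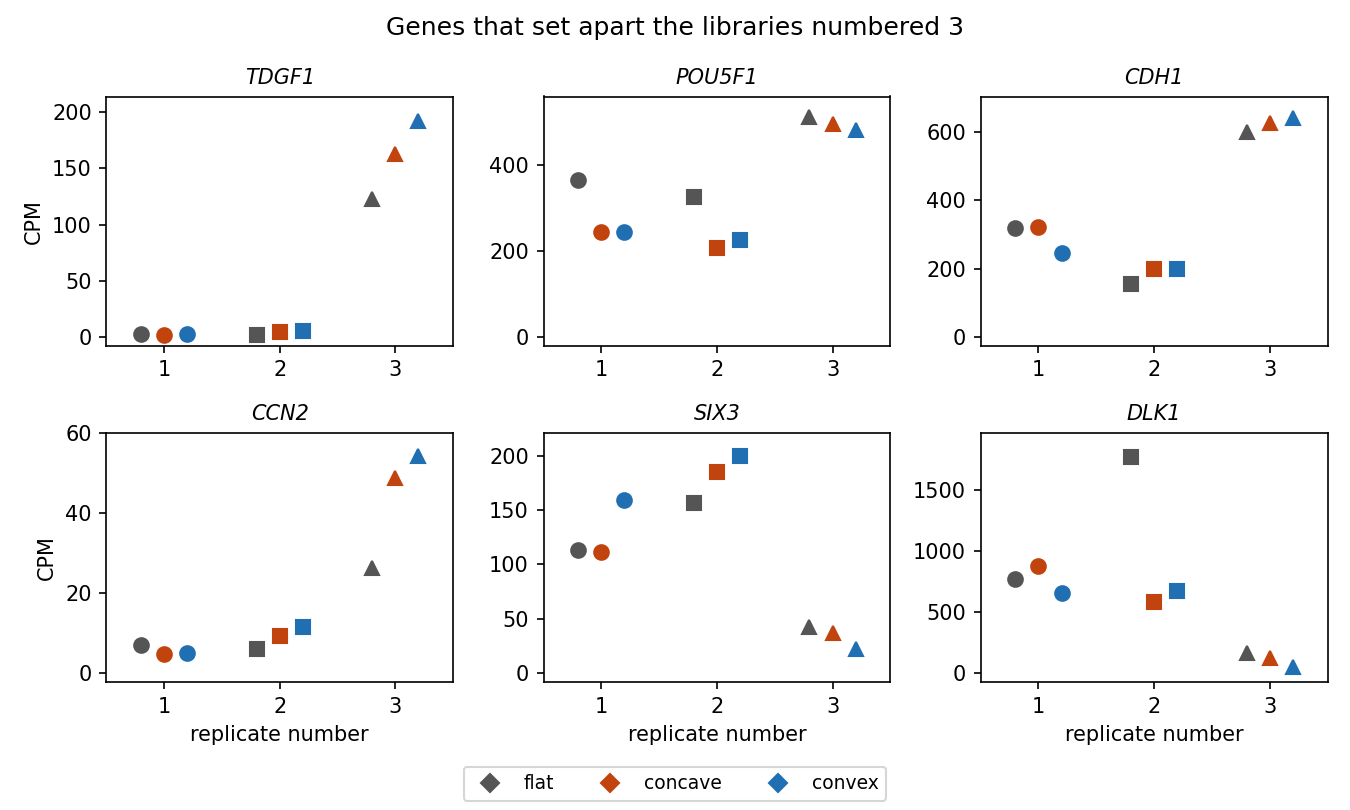
CPM of TDGF1, POU5F1, CDH1, CCN2, SIX3 and DLK1 by library number (x axis), 1 marker per library, coloured by group. TDGF1 lay between 122.9 and 192.5 CPM in the libraries numbered 3 and at most at 4.73 CPM in the other 6.

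Plate shape as such changed no gene past the threshold. An F test among flat, concave and convex groups called 0 of 23075 genes (edgeR quasi-likelihood, smallest adjusted p = 0.971; 897 genes at an unadjusted p under 0.05, where chance gives 1154). With the replicate number as a block it called 0, with 2035 genes at an unadjusted p under 0.05. DESeq2 and limma voom called 0, with 1366 and 784 such genes. The chance count of 1154, here and below, takes p-values as uniform. Other splits drawn from the 9 libraries gave from 51 to 4447 genes at that p, so 1154 is a poor measure of chance here. Without flat 2 there were 266 such genes, without flat 3 3627, without concave 2 486, without concave 3 1413, without convex 1 435, without convex 2 538 and without convex 3 394, and 0 called each time. The power of the F test was not simulated. In counts simulated from these groups with known changes, edgeR's tests of 2 groups found 93.9%, 83.3% and 98.5% of 4-fold changes, in the order concave against flat, convex against flat and concave against convex, but 22.4%, 22.4% and 31.3% of 2-fold ones and at most 2.99% of 1.5-fold ones. The simulated genes were independent and had the same spread in every group, with no difference by replicate number and no outlying library. Power in the real data may therefore differ from these values. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

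Concave against flat cultures asked what concave bending of the plate does to the transcriptome. Messenger RNAs of the translation and respiration machinery fell as groups in concave cultures: all 29 cytosolic ribosomal protein mRNAs and all 28 nuclear-encoded respiratory chain mRNAs tested were lower. Interferon response, histone and heat shock mRNAs fell too, each with some members the other way. Extracellular matrix, integrin, mechanosensitive channel and mitochondrially encoded mRNAs rose. No single gene passed the threshold, and no list passed when the correlation between its genes was estimated from the data. The ribosomal list had a median log2 fold change of -0.65 (camera adjusted p = 3.52e-20; adjusted p = 0.742 with an estimated correlation). RPL8 (ENSG00000161016, chromosome 8, 144789765 to 144792587) stood at 1187 ± 134 against 1971 ± 874 CPM in flat. For the respiratory chain the median was -0.61 (camera adjusted p = 3.41e-16; adjusted p = 0.742 with an estimated correlation). NDUFA2 (ENSG00000131495, chromosome 5, 140638740 to 140647785) stood at 20.6 ± 1.94 against 37.6 ± 20.2 and COX6B1 (ENSG00000126267, chromosome 19, 35648223 to 35658861) at 99.02 ± 14.3 against 166 ± 75.4 CPM. Both rested largely on flat 2: the ribosomal median was -0.23 without flat 2 (camera adjusted p = 9.81e-11) and the respiratory one -0.20 without flat 2 (2.01e-08). Between libraries of the same number, 1, 2 and 3, the ribosomal medians were -0.35, -1.44 and 0.08 and the respiratory ones -0.35, -1.30 and 0.089. Short transcripts were high in flat 2, and a correction for transcript length left medians of -0.37 for the ribosomal and -0.33 for the respiratory list, and of -0.42 for both in convex against flat cultures. Interferon response mRNAs had a median of -0.33, with 17 of 26 lower (camera adjusted p = 0.00692; adjusted p = 0.742 with an estimated correlation). That median was -0.16 without flat 2 and -0.14 after the length correction, and -0.29, -0.54 and -0.0013 by number. ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014540) stood at 14.3 ± 1.61 against 29.7 ± 16.3 CPM and HLA-C (ENSG00000204525, chromosome 6, 31268749 to 31272130) at 213 ± 21.99 against 292 ± 70.99.

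Matrix, adhesion and channel mRNAs rose in concave against flat cultures by camera with the preset correlation, but none of the 3 lists passed after a correction for transcript length. The corrected medians were 0.073 for matrix (camera adjusted p = 0.991, with a test in the opposite direction), 0.034 for integrins (0.738) and 0.15 for channels (0.421). Flat 2 had the lowest list mean of the 9 libraries for each of the 3 lists (-0.53, -0.64 and -0.52 log2 units). The extracellular matrix list had a median of 0.28, 28 of 34 higher (camera adjusted p = 0.0226; adjusted p = 0.824 with an estimated correlation). The matrix median was 0.031 without flat 2 (camera adjusted p = 0.607), 0.33 without flat 3 (camera adjusted p = 0.0561), 0.15 without concave 1 (camera adjusted p = 0.266) and 0.17 without concave 3. COL5A1 (ENSG00000130635, chromosome 9, 134641774 to 134844843) stood at 146 ± 18.3 against 115 ± 17.6 CPM and TNC (ENSG00000041982, chromosome 9, 115019578 to 115118257) at 41.7 ± 12.1 against 27.9 ± 7.695. Integrin and focal adhesion mRNAs had a median of 0.20, 22 of 28 higher (camera adjusted p = 0.0167; adjusted p = 0.901 with an estimated correlation). The integrin median was 0.033 without flat 2 (camera adjusted p = 0.712) and 0.40 without flat 3. ITGAV (ENSG00000138448, chromosome 2, 186590065 to 186680901) gave 42.1 ± 9.69 against 31.7 ± 8.79 CPM. Mechanosensitive channel and calcium entry mRNAs had 0.24, 20 of 24 higher (camera adjusted p = 0.0226; adjusted p = 0.824 with an estimated correlation). The channel median was 0.069 without flat 2 (camera adjusted p = 0.545), 0.40 without flat 3 and 0.22 without concave 1 (camera adjusted p = 0.143). PKD2 (ENSG00000118762, chromosome 4, 88007668 to 88077777) gave 102 ± 16 against 70.05 ± 25.8 CPM. By library number the medians were 0.16, 0.53 and -0.0035 for matrix, 0.12, 0.76 and -0.15 for integrins and 0.15, 0.61 and -0.034 for channels. All 13 mitochondrially encoded mRNAs were higher, with a median of 0.38 (camera adjusted p = 0.0167; adjusted p = 0.916 with an estimated correlation) and -0.18, 0.60 and 0.59 by number. It was 0.17 without flat 2 (camera adjusted p = 0.116), 0.59 without concave 1 and 0.018 without concave 3 (camera adjusted p = 0.894), the last with a test in the opposite direction. MT-ND5 (ENSG00000198786, the mitochondrial genome, 12337 to 14148) stood at 3447 ± 1072 against 2124 ± 1109 CPM, and reads from nuclear copies of mitochondrial genes cannot be separated from it here. Mitochondrially encoded genes took 7.30%, 5.70% and 7.63% of counts in flat libraries 1, 2 and 3, 6.57%, 7.77% and 10.5% in concave and 7.63%, 8.0% and 9.33% in convex ones.

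Heat shock mRNAs had a median of -0.14 in concave against flat cultures, 16 of 19 lower (camera adjusted p = 0.0167; adjusted p = 0.916 with an estimated correlation), with HSPB1 (ENSG00000106211, chromosome 7, 76302544 to 76304295) at 64.8 ± 25.1 against 99.6 ± 18.9 CPM. The heat shock median was -0.22 without flat 1, -0.10 without flat 3 (camera adjusted p = 0.547), -0.032 without concave 1 (camera adjusted p = 0.555) and -0.35 without concave 3, -0.051 after the length correction, and -0.39, -0.21 and -0.011 by number. Histone mRNAs had a median of -0.34, 14 of 21 lower (camera adjusted p = 0.0463; adjusted p = 0.742 with an estimated correlation and 0.0671 with the replicate block), with H1-2 (ENSG00000187837, chromosome 6, 26055787 to 26056428) at 24.1 ± 6.92 against 33.2 ± 4.502 CPM. It was -0.16 without flat 3 (camera adjusted p = 0.505), -0.069 without concave 1 (camera adjusted p = 0.532) and -0.32 without convex 3 (camera adjusted p = 0.0549), -0.20 after the length correction (camera adjusted p = 0.421), and -0.34, -0.16 and -0.18 by number. Most replication-dependent histone mRNAs carry no poly(A) tail, so poly(A) selection recovers a part of them. Among single genes averaging at least 5 CPM, DDX39B (ENSG00000198563, chromosome 6, 31530219 to 31542448) had the smallest p and did not pass (edgeR adjusted p = 0.841). It stood at 244 ± 26.4 against 153 ± 30.1 CPM in flat (log2 fold change 0.67, SE 0.175). Also short of the threshold were MRNIP (ENSG00000161010, chromosome 5, 179835133 to 179862173) at 24.5 ± 2.22 against 16.6 ± 2.16, SNCG (ENSG00000173267, chromosome 10, 86958618 to 86963260) at 24.1 ± 5.09 against 44.4 ± 17.9 and the pseudogene RPL7AP6 (ENSG00000242071, chromosome 14, 69885340 to 69886140) at 17.1 ± 2.93 against 30.4 ± 11.9. Concave libraries differed from flat ones by 0 called genes (edgeR quasi-likelihood, smallest adjusted p = 0.841; 1047 at an unadjusted p under 0.05, 456 higher and 591 lower, against 1154 by chance). DESeq2 and limma voom called 0, with 1225 and 930 at an unadjusted p under 0.05, and the fit with the replicate number as a block called 0, with 2046. The number at an unadjusted p under 0.05 was 388 without flat 2, 4096 without flat 3, 684 without concave 1, 205 without concave 2, 2074 without concave 3, 663 without convex 1 and 693 without convex 2. Adjusted over the list alone, 0 members of every list were called. Lists called numbered 9 of 35 by camera with the preset correlation, 0 with an estimated one and 0 by fry (0 at an unadjusted p under 0.05).

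Convex against flat cultures asked the same of convex bending. Ribosomal protein and nuclear-encoded respiratory chain mRNAs again fell, with 29 of 29 and 27 of 28 lower, and interferon response mRNAs fell with 15 of 26 lower. Hypoxia and glycolysis mRNAs fell, 23 of 26 lower. Integrin and mitochondrially encoded mRNAs rose. None of these 6 lists passed with an estimated correlation (smallest adjusted p = 0.923), and without flat 2 neither hypoxia (camera adjusted p = 0.164) nor integrin mRNAs (0.135) passed. The ribosomal median was -0.76 (camera adjusted p = 6.86e-20; adjusted p = 0.923 with an estimated correlation), -0.34 without flat 2 and -0.51, -1.26 and -0.24 by number. RPL32 (ENSG00000144713, chromosome 3, 12834485 to 12841588) stood at 554 ± 57.6 against 992 ± 408 CPM in flat. The respiratory chain median was -0.72 (camera adjusted p = 1.03e-15; adjusted p = 0.923 with an estimated correlation), -0.34 without flat 2 and -0.48, -1.15 and -0.26 by number. COX5B (ENSG00000135940, chromosome 2, 97646040 to 97648383) stood at 94.97 ± 10.4 against 175 ± 78.6 CPM. Adjusted over the list alone, 29 of 29 ribosomal and 22 of 28 respiratory chain mRNAs were called by edgeR, and 0 of every other list. The smallest of these edgeR adjusted p-values were 0.0276 and 0.0425. The correlation estimated between the members was 0.969 and 0.721, so these calls are far from independent. Interferon response mRNAs had a median of -0.35 (camera adjusted p = 0.00327; adjusted p = 0.923 with an estimated correlation). Their median was -0.11 without flat 2, -0.58 without flat 3 and -0.57 without convex 1, -0.16 after the length correction, and -0.16, -0.62 and -0.28 by number. B2M (ENSG00000166710, chromosome 15, 44711487 to 44718877) stood at 78.5 ± 8.08 against 126 ± 27.2 CPM and BST2 (ENSG00000130303, chromosome 19, 17402939 to 17405648) at 133 ± 36.9 against 300.3 ± 157, and reads of HLA class I genes can be exchanged between paralogs. The hypoxia median was -0.33 (camera adjusted p = 0.0101; adjusted p = 0.929 with an estimated correlation), -0.15 without flat 2 (camera adjusted p = 0.164) and -0.31 without convex 2 (camera adjusted p = 0.0979), and -0.17, -0.70 and -0.018 by number. TPI1 (ENSG00000111669, chromosome 12, 6867119 to 6870948) stood at 543 ± 10.6 against 887 ± 301 CPM.

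Integrin and focal adhesion mRNAs had a median of 0.29 in convex against flat cultures, 25 of 28 higher (camera adjusted p = 0.00217; adjusted p = 0.923 with an estimated correlation). That median was 0.11 without flat 2 (camera adjusted p = 0.135) and 0.49 without flat 3, 0.083 after the length correction (camera adjusted p = 0.47), and 0.14, 0.79 and 0.092 by number. ITGB8 (ENSG00000105855, chromosome 7, 20330702 to 20415754) stood at 20.6 ± 2.32 against 13.1 ± 5.02 CPM and ITGAV at 44.03 ± 1.86 against 31.7 ± 8.79. Mitochondrially encoded mRNAs had 0.39, 12 of 13 higher (camera adjusted p = 0.0101; adjusted p = 0.929 with an estimated correlation). The mitochondrial median was 0.23 without convex 3 (camera adjusted p = 0.0945), 0.64 after the length correction, and 0.18, 0.63 and 0.40 by number. MT-ND5 stood at 3685 ± 622 CPM. In the check for pairing these groups passed the minimum of 0.1, which alone does not show that numbers 1 and 2 were paired. With the replicate number as a block, FGF and ERK targets (camera adjusted p = 0.00633), YAP and TEAD targets (0.0165) and extracellular matrix mRNAs (0.024) also passed. Their medians without the block were 0.43, 0.33 and 0.31. None of them passed when the correlation was estimated in that fit (adjusted p = 0.772 for each with an estimated correlation), and in the fit without the block leaving out flat 2 gave medians of 0.24, 0.21 and 0.10. With length correction the matrix test turned to the opposite direction and did not pass, with the block and without it. Single genes stayed short of the threshold. Among genes averaging at least 5 CPM, the smallest p belonged to ENSG00000242588 (chromosome 7, 128574751 to 128626473), a processed transcript at 73.9 ± 10.5 against 39.8 ± 8.87 CPM (log2 fold change 0.89, SE 0.205, edgeR adjusted p = 0.513). It was followed among the higher genes by ENSG00000291066, which has no position in GENCODE v29, at 11.9 ± 1.73 against 5.64 ± 1.22 and the pseudogene PI4KAP2 (ENSG00000183506, chromosome 22, 21473000 to 21517533) at 33.2 ± 1.25 against 20.6 ± 2.41 CPM. Among the lower genes of that level the smallest p belonged to TMEM141 (ENSG00000244187, chromosome 9, 136791355 to 136793257) at 5.46 ± 0.577 against 11.2 ± 4.26, SNCG at 21.6 ± 2.88 against 44.4 ± 17.9 and PLAC1 (ENSG00000170965, chromosome X, 134565838 to 134764322) at 3.65 ± 0.912 against 7.69 ± 1.59. Convex libraries differed from flat ones by 0 called genes (edgeR quasi-likelihood, smallest adjusted p = 0.513; 2135 at an unadjusted p under 0.05, 931 higher and 1204 lower, against 1154 by chance). The block raised that number to 4222 with 0 called (edgeR smallest adjusted p = 0.264). Limma voom called 0, with 2183 at an unadjusted p under 0.05, and DESeq2 called 1, ENSG00000270871, with 2587. The number at an unadjusted p under 0.05 was 815 without flat 2, 5831 without flat 3, 1152 without convex 1 and 922 without convex 3. Camera called 6 of 35 lists, 9 with the block and 0 with an estimated correlation, and fry called 0 (1 at an unadjusted p under 0.05).

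Concave against convex cultures tested whether the direction of bending mattered. Hypoxia and glycolysis mRNAs were higher in the concave group, all 26 of them, but not once concave 1 was left out. FGF and ERK target mRNAs were lower in concave than in convex cultures, 17 of 21, and ribosomal protein mRNAs slightly higher, 28 of 29. None of the 3 passed with an estimated correlation (adjusted p = 0.982 for each), and after a correction for transcript length neither of the last 2 did at the preset one, with medians of -0.16 for FGF and ERK targets (camera adjusted p = 0.0673) and 0.057 for ribosomal mRNAs (0.132). The hypoxia median was 0.52 (camera adjusted p = 8.84e-14; adjusted p = 0.982 with an estimated correlation), -0.16 without concave 1 (camera adjusted p = 0.115) and 0.84 without concave 2, and 1.37, -0.04 and 0.034 by number. In concave 1, SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42959176) stood at 793.5 CPM against 198.3 and 290.9 in concave 2 and 3, LDHA (ENSG00000134333, chromosome 11, 18394388 to 18408425) at 852.1 CPM against 189.8 ± 19.97 in convex cultures. Of the 26 members, 22 had their highest value of the 9 libraries in concave 1. NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) gave 22.1 ± 35.2 against 3.42 ± 2.78 CPM. For FGF and ERK targets the median was -0.20 (camera adjusted p = 0.0284; adjusted p = 0.982 with an estimated correlation), and -0.37, -0.17 and -0.19 by number. It was 0.044 without concave 1 (camera adjusted p = 0.48), -0.32 without concave 2, -0.47 without concave 3, -0.35 without convex 1, -0.20 without convex 2 (camera adjusted p = 0.112) and 0.0067 without convex 3 (camera adjusted p = 0.711). ETV5 (ENSG00000244405, chromosome 3, 186046308 to 186110318) stood at 6.63 ± 4.16 against 9.83 ± 5.07 CPM and FGF2 (ENSG00000138685, chromosome 4, 122826708 to 122898236) at 65.9 ± 11.9 against 83.9 ± 32.01. The ribosomal median was 0.11 (camera adjusted p = 0.0207; adjusted p = 0.982 with an estimated correlation), and 0.15, -0.17 and 0.32 by number, and it was 0.11 without concave 1 (camera adjusted p = 0.151), 0.22 without concave 2, 0.062 without concave 3 (camera adjusted p = 0.61) and 0.068 without convex 3 (camera adjusted p = 0.41). RPL32 stood at 631 ± 94.7 against 554 ± 57.6 CPM.

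Concave and convex groups also passed the minimum of 0.1 in the check for pairing, with the same limit for numbers 1 and 2. With the block, SRF and MRTF targets (camera adjusted p = 0.0205), integrin (0.0296), p53 target (0.0353) and S phase mRNAs (0.0296) were also lower in concave than in convex cultures. Their medians without the block were -0.085, -0.094, -0.094 and -0.056. None of the 4 passed when the correlation was estimated in that fit (adjusted p = 0.849 for each with an estimated correlation). In the fit without the block, leaving out concave 1 gave SRF and S phase medians of 0.039 and 0.089, with a test in the opposite direction, and a p53 target median of -0.023. Among genes averaging at least 5 CPM, those higher in concave cultures with the smallest p, none past the threshold (edgeR adjusted p = 1), were EIF3C (ENSG00000184110, chromosome 16, 28688558 to 28735730) at 48.5 ± 22.1 against 24.1 ± 8.57 CPM (log2 difference 1.01, SE 0.366) and its near-identical copy EIF3CL (ENSG00000205609, chromosome 16, 28379579 to 28403879) at 12.1 ± 16.4 against 3.15 ± 0.363. EIF3CL rested on concave 3, with 2.19, 3.11 and 31.04 CPM in concave 1, 2 and 3, and was lower in concave cultures without that library (log2 difference -0.24). NDRG1 came next, and it was lower without concave 1, which had 62.74 CPM against 1.61 and 1.82 in concave 2 and 3. Among the lower genes of that level they were SALL3 (ENSG00000256463, chromosome 18, 78980275 to 79002677) at 16.2 ± 0.845 against 22.4 ± 3.37, ARC (ENSG00000198576, chromosome 8, 142611044 to 142614472) at 4.68 ± 1.36 against 7.43 ± 2.78 and SAPCD2 (ENSG00000186193, chromosome 9, 137062124 to 137070588) at 22.97 ± 1.31 against 27.6 ± 0.654. Concave and convex libraries differed by 0 called genes (edgeR quasi-likelihood, smallest adjusted p = 1; 65 at an unadjusted p under 0.05, 42 higher in concave and 23 lower, against 1154 by chance). Other splits of these 6 libraries gave from 46 to 2659 genes with such a p, so a count under 1154 is no sign that the groups are alike. With the block 147 genes had such a p and 0 were called. DESeq2 and limma voom called 0, with 76 and 65 at an unadjusted p under 0.05. That number was 107 without flat 2, 148 without concave 2 and 147 without concave 3. Adjusted over the list alone, 0 members of every list were called. Camera called 3 of 35 lists, 7 with the block and 0 with an estimated correlation, and fry called 0 (0 at an unadjusted p under 0.05).

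**Figure D4:**
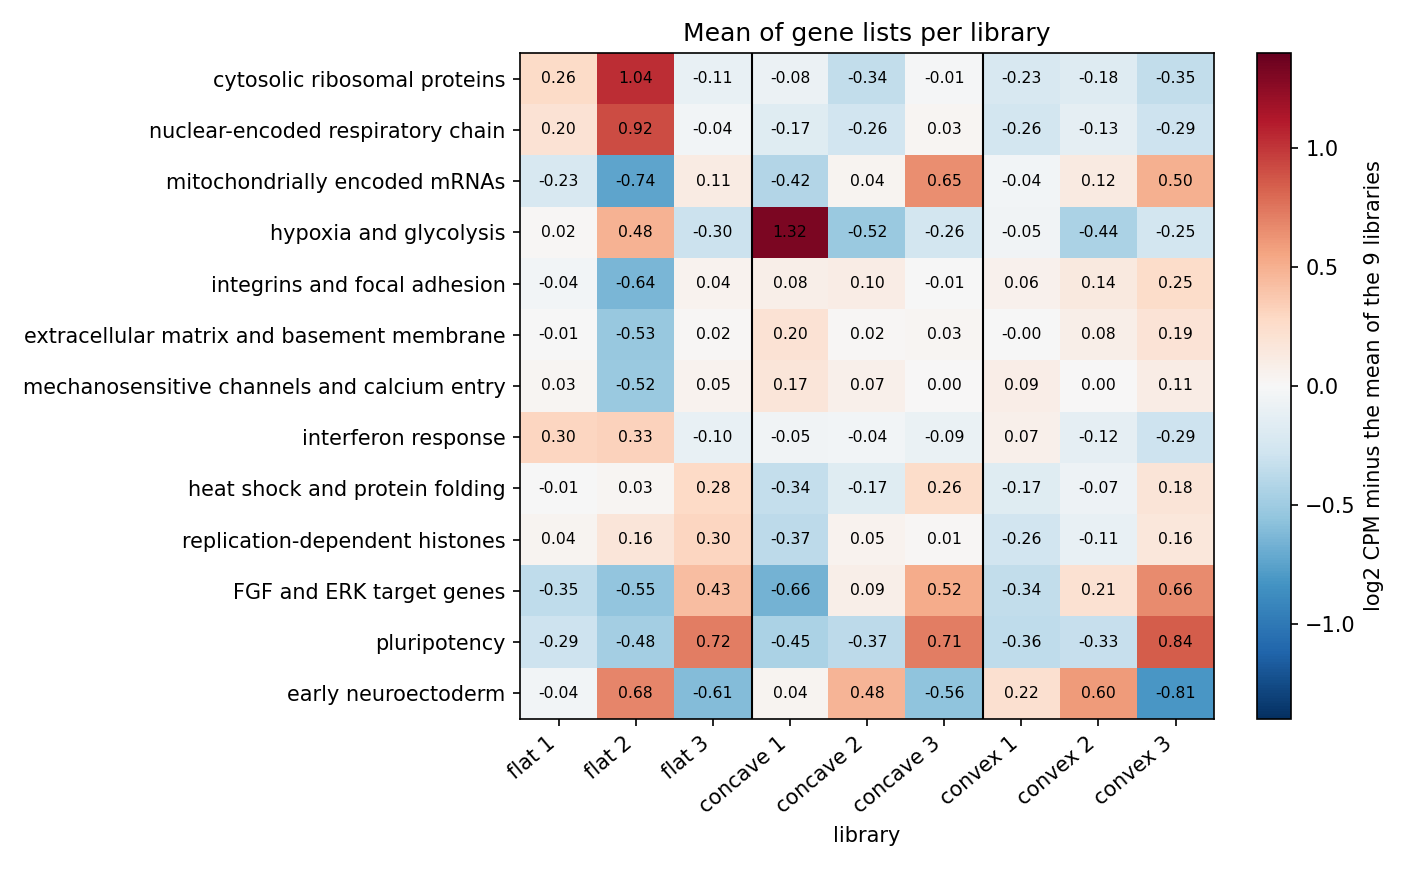
Mean log2 CPM of 13 gene lists in the 9 libraries, each gene centred on its mean over the 9 (colour, log2 units). Ribosomal and respiratory chain mRNAs were highest in flat 2 (1.04 and 0.92) and hypoxia mRNAs in concave 1 (1.32).

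The differences of concave and convex cultures from flat ran together across genes, and both used the same flat libraries. Across 23075 genes the log2 differences had a Pearson correlation of 0.861, and 86.4% of genes had the same sign. Unchanged groups, drawn 20 times with each group's own spread, gave a mean correlation of 0.609 and 71.9% of genes with the same sign. With the covariance by library number kept as well they gave 0.734 (0.722 to 0.745) and 79.2%. The covariance was 0.219, against 0.143 and 0.11 in these draws. For genes averaging at least 5 CPM the correlation was 0.944 against 0.635 and 0.872, and the covariance 0.107 against 0.0677 and 0.0513. Part of the excess may come from the shared flat libraries, since genes were drawn one by one and real libraries deviate in many genes at once. Flat libraries had the widest spread, with a median SD of 0.318 log2 units against 0.218 in concave and 0.167 in convex ones. No gene was called in both, since edgeR called 0 in each (1047 and 2135 at an unadjusted p under 0.05), DESeq2 0 and 1 and limma voom 0 and 0. Genes are not independent replicates, and 3 flat libraries cannot be divided to give each curvature its own control.

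Lineage and patterning programs showed no change with curvature that passed the test in the fit of all 9 libraries without a block, where 24 of the 35 lists passed in none of the comparisons, but some passed with a library left out. In concave against flat, pluripotency and non-neural ectoderm mRNAs had medians of -0.35 (camera adjusted p = 0.036) and -0.48 (0.0222) without concave 3 and early neuroectoderm mRNAs -0.30 (0.029) without concave 2. In convex against flat, non-neural ectoderm mRNAs had -0.67 (camera adjusted p = 0.0043) without convex 3. Fibroblast, endothelial and blood markers tested lower without flat 2, with medians of 0.0093 in concave (camera adjusted p = 0.00968) and -0.12 in convex against flat (0.0124). Between concave and convex cultures the direction for pluripotency, non-neural ectoderm and early neuroectoderm mRNAs depended on the library left out, with pluripotency medians of -0.35 without concave 3 and 0.28 without convex 3 (camera adjusted p = 0.000237 and 0.00425). These fits had no block, so leaving out a library unbalances the replicate numbers and mixes curvature with number. By number the pluripotency medians, concave minus convex, were -0.064, -0.0041 and -0.086. The values that follow are from all 9 libraries. Early neuroectoderm mRNAs had medians of -0.10 in concave and -0.076 in convex against flat (smallest camera adjusted p over the 3 comparisons, 0.699), and pluripotency mRNAs 0.082 and 0.16 (0.566). Medians and smallest camera adjusted p, in the same order, were 0.20 and 0.092 (0.792) for neuronal differentiation, 0.11 and 0.13 (0.27) for neural crest and 0.026 and 0.0087 (0.594) for non-neural ectoderm. For mesoderm and endoderm they were -0.054 and -0.19 (0.396), for amnion and trophectoderm 0.04 and 0.013 (0.781) and for fibroblast, endothelial and blood markers 0.004 and -0.15 (0.529). Posterior neural patterning mRNAs had -0.13 and -0.39 (0.33), ventral patterning and hedgehog targets 0.26 and 0.28 (0.182) and dorsal patterning mRNAs -0.019 and 0.011 (0.864). Among signalling targets that passed in none, those of BMP and TGF-beta had 0.10 and 0.092 (0.529), those of WNT 0.09 and 0.15 (0.6) and those of Notch -0.13 and -0.16 (0.594). Immediate early genes had 0.029 and 0.17 (0.342), YAP and TEAD targets 0.18 and 0.33 (0.0664) and SRF and MRTF targets -0.0036 and 0.093 (0.109). Apical constriction and planar polarity genes gave 0.19 and 0.19 (0.077) and apicobasal polarity and junction genes -0.033 and -0.08 (0.6). Targets of p53 gave -0.10 and 0.017 (0.109), unfolded protein response genes -0.11 and -0.11 (0.0877) and cholesterol biosynthesis genes 0.14 and 0.13 (0.529). S phase genes gave -0.091 and -0.045 (0.0674) and mitosis genes 0.08 and 0.04 (0.792). Of lists called elsewhere, hypoxia mRNAs had a median of 0.15 in concave against flat (camera adjusted p = 0.735) and FGF and ERK targets 0.20 (0.581). That hypoxia median hides opposite values: it was -0.49 without concave 1 (camera adjusted p = 1.38e-08) and 0.53 without flat 2 (0.0114). The FGF and ERK median was 0.45 without concave 1 (camera adjusted p = 0.00137) and 0.012 without flat 2 (0.673, with a test in the opposite direction). Heat shock and histone mRNAs had -0.14 (0.185) and -0.20 (0.119) in convex against flat. There the matrix list had 0.31 (camera adjusted p = 0.077) and the mechanosensitive channel list 0.20 (0.096). Between concave and convex cultures the lists called against flat alone had medians from -0.094 for integrins (camera adjusted p = 0.0581) to 0.10 for the respiratory chain (0.0546). The respiratory chain list passed there with some libraries left out, among them flat 2 (median 0.115, camera adjusted p = 0.000855) and concave 1 (0.126, camera adjusted p = 0.0356). Matrix mRNAs had -0.028 there, channel mRNAs -0.02, heat shock mRNAs -0.047, mitochondrially encoded mRNAs -0.045, histone mRNAs 0.059 and interferon response mRNAs 0.0044 (camera adjusted p from 0.362 to 0.981). A list's median, mean and test differed in sign for 8, 4 and 9 lists in concave against flat, convex against flat and concave against convex, 0 of which were called.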

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

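The lists, the replicate block and the values without each library were planned, and the length correction and every test of an explanation, splits included, were chosen only after the results were seen. The difference between concave and convex cultures was itself tested, and 3 lists passed at the preset correlation: hypoxia and glycolysis (median log2 difference 0.52), FGF and ERK targets (-0.20) and cytosolic ribosomal proteins (0.11). With an estimated correlation (smallest adjusted p = 0.982) and by fry (0.997) 0 passed, and the ribosomal list did not pass without concave 1, concave 3 or convex 3 (camera adjusted p = 0.151, 0.61 and 0.41). No list, 0 of 35, and 0 of 86 named genes had every concave library on one side of the flat libraries and every convex library on the other.

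Hypoxia and glycolysis mRNAs were higher in concave than in convex cultures. Without concave 1 the median was -0.16 (camera adjusted p = 0.115), so the difference rested on that library, whose list mean of 1.32 lay above the next highest, flat 2, at 0.485. A trend with transcript length was argued against, since after its correction the gap to the next library was 0.88. A rise common to concave cultures was argued against, since concave 2 and 3 had list means of -0.52 and -0.26. Low oxygen, crowding or bending in the cells of concave 1 is a possible explanation, as is a technical difference of that library. Neither was tested, and the labels do not say whether concave 1 was a separate culture. All 10 splits of the 6 libraries called at least as many lists as the real one, 3 against a highest other of 15, and splits of 6 are too few for a share under 0.05.

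Ribosomal protein and respiratory chain mRNAs were lower in both curved groups than in flat. Transcript length ran with the libraries, with a Spearman correlation of -0.64 in flat 2, -0.31 in flat 1, 0.20 in flat 3, 0.33, 0.45 and -0.17 in concave 1, 2 and 3, and 0.32 to 0.48 in the convex libraries, and both lists hold short transcripts (medians 1004 and 785 bp). After a length correction the ribosomal medians were -0.37 and -0.42 in concave and convex against flat, and they lay -0.19 and -0.20 below genes of like length, 27 of 29 and 28 of 29 members below. The respiratory chain medians lay -0.145 and -0.186 below, with fewer members, 23 and 20 of 28, below. Without flat 2 the ribosomal median was -0.23 in concave against flat, so flat 2 alone carries much of it and may not carry all. In list means, flat 1 (ribosomal 0.263, respiratory 0.202) lay above every curved library. Flat 3 (-0.105 and -0.0415) lay above every convex library but below concave 3 (-0.0148 and 0.0327). What stays open is a length trend not fully removed, flat 2 as an unusual culture or library, and a response to bending, which cannot be told apart with 3 flat libraries and no call at an estimated correlation.

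FGF and ERK targets were lower in concave than in convex cultures at every library number (-0.37, -0.17 and -0.19), without a call at an estimated correlation (adjusted p = 0.982). The median was 0.044 without concave 1 and 0.0067 without convex 3, in fits without the block, where leaving out a library unbalances the numbers. It was -0.16 after the length correction (camera adjusted p = 0.0673), and the cause was not tested.

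EdgeR called 0 genes for each pair of groups, a count that every split reaches, so splits were compared at an unadjusted p under 0.05. There the counts were 1047 in concave against flat, reached by 5 of 10 splits (highest other 4304), 2135 in convex against flat, reached by 3 (highest other 3889), and 65 in concave against convex, reached by 9 (highest other 2659). DESeq2 gave 1225, 2587 and 76 such genes and voom 930, 2183 and 65. Lists called numbered 9 in concave against flat, reached by 7 of 10 splits (highest other 20), and 6 in convex against flat, reached by 9 of 10 (highest other 19). These splits are too few for a share under 0.05. For the pairs of groups that the numbers paired, among splits that part every pair of numbers, as the real one does, the highest others were 337 genes against 2135 for convex against flat and 127 against 65 for concave against convex, and 7 to 14 lists against 6 and 4 to 9 against 3. For concave against flat, which the numbers did not pair, the highest other was 3253 genes against 1047, and 6 to 7 lists against 9. Each of these comparisons rests on 4 splits, the real one included. In each comparison the split with the most genes at an unadjusted p under 0.05 put both libraries numbered 3 on the same side, which points to a structure by number. Among the 3 groups edgeR called 0 genes and gave 897 at an unadjusted p under 0.05 (1366 by DESeq2 and 784 by voom). Of 40 drawn splits, 18 gave as many as 897 (highest other 4447), so chance was not excluded, while a split by replicate number called 2597. These splits were drawn without regard to the replicate numbers, so differences by number enter their counts. Splits that part the numbers were not set apart for this test.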

How the results depend on the processing

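Most alternatives were planned. Those with a term for libraries numbered 3, libraries numbered 1 and 2 only, flat 2 and concave 1 left out together, quality weights, length correction and the block with an estimated correlation were chosen only after the results were seen.

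No gene was called between any pair of groups under the 27 alternatives run, except by DESeq2 and by unadjusted p with a fold minimum. DESeq2 called 1 gene in convex against flat, ENSG00000270871, with a log2 fold change of 1.95 in edgeR. Its edgeR adjusted p was 0.513. By unadjusted p under 0.05 and an absolute log2 fold change of at least 1 the counts were 349, 695 and 58 for concave against flat, convex against flat and concave against convex. With quality weights voom gave 6218, 6317 and 449 genes at an unadjusted p under 0.05 and 0 called (smallest adjusted p 0.0704, 0.0634 and 1), and edgeR on numbers 1 and 2 only gave 5300, 5081 and 114 and 0 called. For 119 results on named genes, all 2843 alternative values stayed on the same side of the threshold, and 102 values, none past it, from 31 of these results and 15 genes, had another sign.

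Lists called in concave against flat fell from 9 to 5 with length correction, to 5 with length correction and the replicate block, and to 0 with an estimated correlation (0 with the replicate block too) and 0 with fry, and ran from 7 (without concave 1) to 14 (without concave 2 or concave 3) with a library left out. In convex against flat they went from 6 to 11 with the stricter filter, 12 with libraries numbered 1 and 2, 10 without flat 2 and concave 1, 0 with an estimated correlation (0 with the replicate block too) and 0 with fry, and 6 to 10 with a library left out (10 without flat 1, flat 3, convex 1 or convex 3). In concave against convex they went from 3 to 6 with library size only, 1 with no filter, 9 with the stricter filter, 7 with the replicate block, 7 with numbers 3 as a block, 7 with numbers 1 and 2, 1 with length correction, 6 with length correction and the block, 0 with an estimated correlation (0 with the replicate block too) and 0 with fry, and 3 to 12 with a library left out (12 without concave 3 or convex 1, 6 without convex 3). The cause was not tested.

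Of the alternative values of lists, 306 kept their call and direction, 99 lost the call, 127 gained it and 20 reversed. Without flat 2 and concave 1 the extracellular matrix median in concave against flat was 0.026 with a test in the other direction, as it was at 0.073 with length correction. Leaving out that pair also gave -0.33 for hypoxia in concave against flat, and 0.045 for FGF targets, -0.16 for hypoxia and 0.17 for mitochondrially encoded mRNAs in concave against convex. With numbers 1 and 2 only the ribosomal median in concave against convex was -0.000259. Where leaving out a library moved a call or a direction in concave against flat, medians ran from -0.49 to 0.53 for hypoxia, -0.21 to 0.28 for cholesterol biosynthesis and 0.018 to 0.59 for mitochondrially encoded mRNAs, and stood at -0.35 for pluripotency, -0.48 for non-neural ectoderm, -0.30 for early neuroectoderm and -0.28 for SRF and MRTF targets. In convex against flat they ran from -0.24 to 0.30 for cholesterol biosynthesis and stood at -0.67 for non-neural ectoderm. In concave against convex they ran from -0.47 to 0.044 for FGF targets, -0.16 to 0.84 for hypoxia, -0.36 to 0.17 for mitochondrially encoded mRNAs, -0.35 to 0.28 for pluripotency, -0.30 to 0.64 for non-neural ectoderm, -0.26 to 0.21 for early neuroectoderm and -0.35 to 0.27 for cholesterol biosynthesis, and stood at 0.42 for amnion. The fits with a library left out had no block, so they also unbalance the replicate numbers. Causes were not tested. Depth limits little here, since replicates differed by far more than sampling noise (chi-square per degree of freedom of at least 19.7), and the spread between libraries sets the precision.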

Other observations

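All tests of this part were chosen only after the results were seen. Libraries numbered 3 stood apart in every group, with 3756 genes called, 2088 of them averaging at least 5 CPM (1122 higher, 966 lower). Only 1 of the 27 splits that set a library of each group apart, this one, called as many genes in edgeR, with a highest other of 0. At an unadjusted p under 0.05 this split gave 7145 genes and the highest other 3091. Number 3 was picked from the 3 numbers after its libraries were seen to stand apart. The 27 splits do not allow for that choice, so they cannot exclude chance. Length was argued against as the whole cause, since 3603 of the genes were also called in the same direction after its correction. A share of undifferentiated cells and no other change could lower the genes of the remaining cells alike, yet 271 genes of at least 5 CPM were lower by more than 1 log2 unit, which needs most of the cells to be of another kind; POU5F1 stood at 496 against 268.5 CPM, L1TD1 at 526 against 179.6 and NANOG at 0.325 against 0.0163. Cultures at an earlier stage of induction may explain it, which was not tested beyond that share of cells, and a part owed to library preparation was not tested either, because the labels give numbers without a date or batch.

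Besides the pluripotency and early neuroectoderm lists, non-neural ectoderm (median 0.89, 8 of 17 called higher; adjusted p = 0.219 with an estimated correlation), FGF and ERK targets (0.65, 9 of 21; 0.287), YAP and TEAD targets (0.61, 11 of 23; 0.282), SRF and MRTF targets (0.51, 13 of 24; 0.28) and cholesterol biosynthesis (0.64, 12 of 25; 0.335) were higher in libraries numbered 3 by camera with the preset correlation. So were amnion (0.86, 4 of 9; 0.101), unfolded protein response (0.49, 8 of 25; 0.287), heat shock (0.34, 6 of 19; 0.335), mitochondrially encoded (0.55, 4 of 13; 0.335) and S phase mRNAs (0.27, 2 of 28; 0.659). Fibroblast, endothelial and blood markers were lower, with a median of -1.22, 5 of 7 called lower and an adjusted p of 0.101 with an estimated correlation. By fry the lists from non-neural ectoderm to these markers had adjusted p from 0.000641 to 0.0258, except S phase at 0.106. The libraries were set apart after they were seen to differ, and no p-value here allows for that choice.

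The weights that voom gave each library for its quality were 3.56, 0.256 and 0.414 for flat 1, 2 and 3, 0.968, 2.66 and 0.41 for concave, and 2.02, 2.33 and 0.531 for convex libraries.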
